A study of Homo sapiens with 26 samples.

How the data were processed

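Replication timing was measured by E/L Repli-seq in human RPE cells. Per the labels' protocols, cells were sorted by DNA content into early and late S phase, BrdU-labelled DNA was immunoprecipitated from 10000 cells of each fraction, and it was amplified as a whole genome before library preparation. The labels name 2 library kits without saying which libraries each made, and do not say when BrdU was added relative to camptothecin. Each of the 13 profiles pairs the early and late library of a replicate, which makes 26 libraries. There were 2 control profiles, 1 profile each of caffeine alone at 2, 7 and 24 h, and 2 profiles each of CPT and of CPT with caffeine at 2 and 7 h.

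Per the submitters' processing notes, cutadapt and Picard were used and the build was hg19 (GRCh37). The aligner is not given in the sources used here. The deposited signal of each library covers windows of 300 kb every 40 kb along the genome, and is already scaled by library. Its values are whole multiples of 1 step per library, so reads per window could be recovered, and 100% of the values came out whole within a tolerance of 0.05 of a read. Only 2 step sizes occur, 0.196 in 12 libraries and 0.216 in 14, and the origin of these factors is not given in the sources used here. The deposited log2 profiles equal log2 of the early over the late signal of the same replicate, within 5e-06. The 5 deposited average tables were not used, since they add no sample.

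Recovered reads in non-overlapping windows ranged from 3853799 to 5867890 per library, with a median of 379 to 626 reads per window. Counting error alone gave a median standard error of 0.088 to 0.102 log2 for the early/late ratio of a window. These errors cover counting only, because amplified reads are not independent molecules. Replicate libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.34 to 5.34, so none was counted as a repeat deposit.

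Windows on chromosomes 1 to 22 were used, and the sex chromosomes were left out. Of 71871 complete autosomal windows, 66742 had a mean signal of at least 25% of the autosomal median. The early/late ratio (E/L) was log2((early + 1)/(late + 1)) on the scaled signal, and each profile was centred on its median. The pseudocount of 1 is about 5 reads, so ratios of sparse windows are slightly understated. The tests per window used every 8th window, 8350 in all, which do not overlap.

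Window tests used limma 3.58.1 (R 4.3.3) on the 10 profiles of the 5 conditions with 2 replicates, with 5 residual degrees of freedom and Benjamini-Hochberg adjustment over windows at 0.05. The plan named edgeR for whole counts and limma for scaled values, and the deposited values are scaled. edgeR 4.0.16 on the recovered reads was added after the data were seen. In data simulated for CPT 7 h against control over 8350 windows, limma recovered 62% of 100 windows changed by 0.5 log2 and 100% of 100 windows changed by 1.0 log2, with 14 calls among unchanged windows. edgeR was run on reads simulated separately with the same windows changed, and recovered 57% and 100% with 7 such calls. The simulations differ, so these values do not rank the 2 tools.

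Consensus timing peaks and valleys were the highest or lowest window within 480 kb on either side in the mean of all 13 profiles, standing at least 0.2 log2 from the mean of the windows 480 kb to either side. This gave 1329 peaks and 1381 valleys. A scalar was taken from each profile for 6 properties. Dynamic range was the SD of E/L over windows, and fine-scale share was the SD of the difference from the 480 kb flanks divided by that SD. Peak prominence and valley depth were the mean differences from the flanks at consensus peaks and valleys, and peak prominence was also taken in the early and late library alone. Scalars were compared by exact two-sided permutation tests over 24 tests adjusted together. Single profiles were the units, so the 2 replicates of a condition counted separately. The 8 profiles with CPT were set against the 5 without, all together and separately at 2 h and 7 h. CPT with caffeine was set against CPT within time points, where 36 arrangements allow no p below 0.0556.

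Windows were also sorted into 5 equal timing classes by the mean of all 13 profiles, class 1 being the earliest. Comparisons, classes, scalars, alternatives and the rule for naming windows were fixed before the data were examined. For CPT against control at each time, the rule took the 5 windows that moved most in each direction among those with adjusted p under 0.05 and both treated replicates beyond both controls, with at most 1 window per chromosome and direction. For other contrasts it took 2, and for the interaction no separation of replicates was required. Differences between timing classes, peaks by class and peak positions were chosen after exploratory results had been seen. Computations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for plots.

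The 6 gene lists fixed in advance were not run, because the gene table used here belongs to another genome build, so windows are named by hg19 coordinates alone. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Alternatives covered centring, scaling to the same SD, quantile normalization, pseudocounts of 0.1 and 10, filters, shifted windows, other peak sets, flanks of 800 kb, other class definitions, a replicate block, the deposited ratios and leaving out each profile.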

Results

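E/L Repli-seq sets DNA copied by cells in early S phase against DNA copied in late S phase, so that a high log2 early/late ratio (E/L) marks a region that replicates early. The cells were human retinal pigment epithelium (RPE) cells, exposed to 1 µM camptothecin (CPT), an inhibitor of topoisomerase I. Some cultures also received 1 mM caffeine, which inhibits the checkpoint kinases ATM and ATR. The data comprised 13 profiles from 26 libraries of 3853799 to 5867890 reads. Control, CPT 2 h, CPT 7 h, CPT+caffeine 2 h and CPT+caffeine 7 h had n = 2, and caffeine alone had 1 profile each at 2, 7 and 24 h. Values below are centred on the autosomal median of each profile unless stated, and all coordinates are hg19.

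Control cells had a deep timing landscape. The earliest class of windows averaged 2.42 ± 0.066 and the latest -0.83 ± 0.089 log2 E/L (SD, n = 2). The dynamic range, the SD of E/L across windows, was 1.25 ± 0.055. At the 1329 consensus timing peaks, spaced 1600 kb apart in the median, E/L stood 1.15 ± 0.026 above the flanks. Across windows, which are not independent replicates, the control profiles correlated at r = 0.989.

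Caffeine alone gave profiles that correlated with control. The latest class lay at -1.38, -0.95 and -1.11 after 2, 7 and 24 h, below both controls, but without centring only the 2 h value (-1.82) did, while those at 7 h (-1.45) and 24 h (-1.51) lay between the controls (-1.65 and -1.40). The profiles at 2, 7 and 24 h had dynamic ranges of 1.40, 1.21 and 1.27 and peak prominences of 1.29, 1.18 and 1.04. Their correlations with control replicate 1 across windows were 0.963, 0.982 and 0.964, and with replicate 2 they were 0.946, 0.973 and 0.953. With 1 profile per time, these differences have no replicate check.

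**Figure D1:**
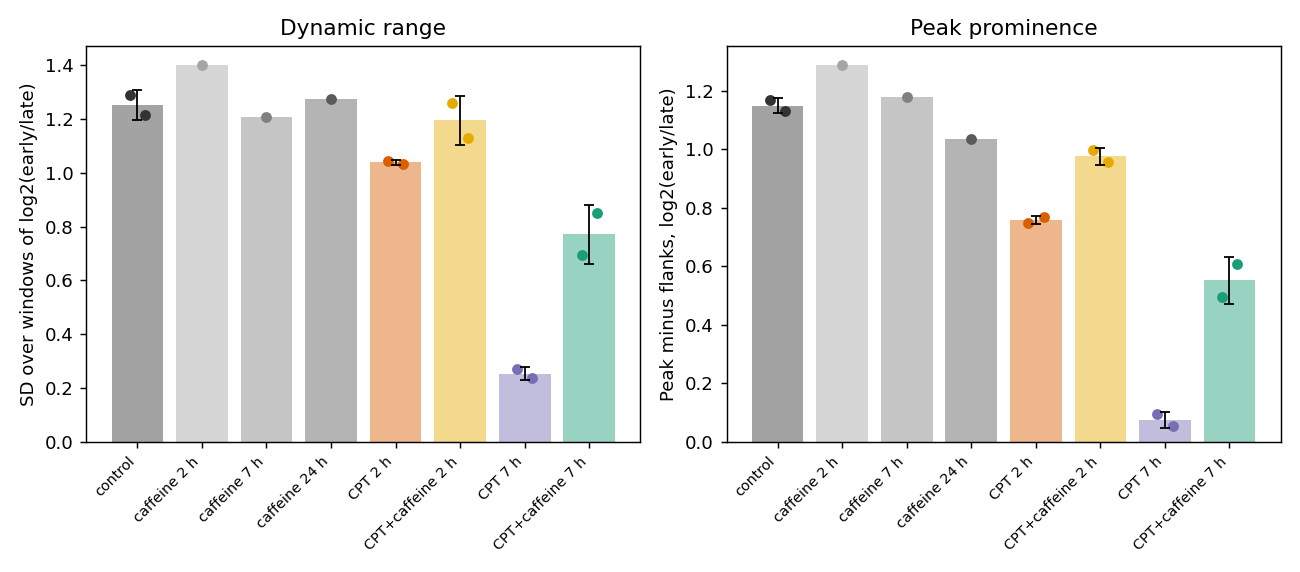
Dynamic range (SD of log2 E/L over windows) and peak prominence (log2 E/L at peaks minus flanks) in each condition; bars are means, points single profiles and error bars the SD where n = 2. The CPT 7 h bars are the lowest in both panels, at 0.253 and 0.074.

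CPT for 2 h flattened the earliest part of the genome most. The earliest class averaged 1.36 ± 0.018 log2 E/L (SD, n = 2) against 2.42 ± 0.066 in control, while class 2 averaged 0.99 ± 0.023 against 1.16 ± 0.091 (uncentred, class 2 turned the other way, at 0.85 against 0.47). The gap between classes 1 and 3 was narrower than in control by -1.09 ± 0.025 log2 (-0.64 with profiles scaled to the same SD), and the gap between classes 3 and 5 was wider by 0.43 ± 0.14. At 1.23 that second gap lay within the 0.95 to 1.37 of caffeine alone, while the gap between classes 1 and 3 was 1.36 against 2.18 to 2.26 in caffeine alone. Peaks in class 1 stood 0.566 ± 0.036 above their flanks against 1.31 ± 0.012 in control, whereas peaks in class 3 stood at 0.876, above the control (0.728 ± 0.076) but within the 0.747 to 1.15 of caffeine alone. The wider gap between classes 3 and 5 depended on how classes were set, and was 0.12 with classes from the control mean.

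The named regions that became later at 2 h moved by over 2 log2. At chromosome 19, 960001 to 1260000, E/L fell by 2.80 log2 (SE 0.204, adjusted p = 9.68e-08, limma). The changes were -2.48 (SE 0.136) at chromosome 11, 640001 to 940000, and -2.48 (SE 0.137) at chromosome 17, 79360001 to 79660000. They were -2.46 (SE 0.153) at chromosome 22, 41600001 to 41900000, and -2.41 (SE 0.184) at chromosome 16, 320001 to 620000. Without centring these falls are smaller and the rises below are larger, because the uncentred median rose from -0.69 in control to -0.14. The windows that became earlier moved less. They were chromosome 16, 960001 to 1260000, up by 0.83 (SE 0.238), chromosome 12, 132800001 to 133100000, up by 0.75 (SE 0.178), and chromosome 1, 228480001 to 228780000, up by 0.74 (SE 0.146). Chromosome 2, 241600001 to 241900000, rose by 0.73 (SE 0.127) and chromosome 5, 81920001 to 82220000, by 0.71 (SE 0.133). Part of these changes was also seen in caffeine alone, at 1 profile per time. Every caffeine profile lay above both controls in the gains on chromosomes 2, 5 and 12, but not on 1 and 16. On chromosome 5 the 24 h value was 1.19, above both CPT 2 h profiles (0.87 and 0.69). In the falls, except on chromosome 17, every caffeine profile lay below both controls. These comparisons with caffeine alone also rest on centring. Without it every caffeine profile lay above both controls in each of these gains, and below both only in the falls on chromosomes 11 and 19. On chromosome 19 caffeine gave 2.99 to 3.23 against 3.91 and 3.72 in control. The chromosome 16 gain did not pass without CPT 2 h replicate 1 (0.60, adjusted p = 0.123, limma) or without control replicate 2 (0.82, adjusted p = 0.0537). The gains on chromosomes 1, 5 and 12 did not pass with quantile normalization, nor that on chromosome 12 with SD scaling.

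At 2 h, limma called 4239 of 8350 windows, of which 313 became earlier and 3926 later relative to the genome median. The direction depends on that centring, because the uncentred median rose from -0.69 ± 0.086 in control to -0.14 ± 0.012 (SD, n = 2). A higher median was not particular to CPT: in caffeine alone it was -0.44, -0.50 and -0.41 after 2, 7 and 24 h, above both controls (-0.75 and -0.63). Without centring, 3616 windows became earlier and 1100 later. The count of earlier windows also rested on single profiles, at 97 without control replicate 2 and 129 without either CPT 2 h replicate. Scaling profiles to the same SD left 2137 calls and quantile normalization left 428.

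**Figure D2:**
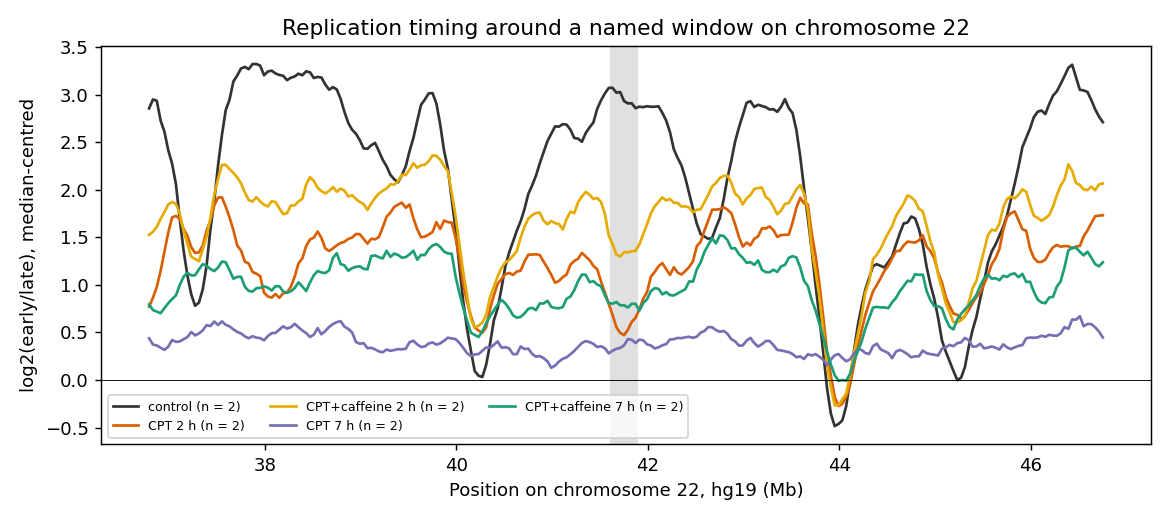
Mean log2 E/L (median-centred) along 10 Mb of chromosome 22 in the 5 conditions with 2 replicates; the grey band is the window from 41600001 to 41900000. In that window the control profiles lie at 3.11 and 2.76 and the CPT 2 h profiles at 0.38 and 0.56.

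After 7 h of CPT the timing landscape was nearly flat. The earliest class averaged 0.34 ± 0.071 and the latest -0.19 ± 0.007 log2 E/L (SD, n = 2), and the dynamic range was 0.253 ± 0.023. Consensus peaks stood 0.074 ± 0.027 above their flanks. The early and late libraries of a profile, which correlated at -0.017 and -0.084 across windows in control, correlated at 0.756 and 0.790. Against control, the gap between classes 1 and 3 changed by -2.03 ± 0.082 and that between classes 3 and 5 by -0.69 ± 0.14, or by -0.29 and -0.19 with profiles scaled to the same SD. The order of windows was kept in part, since the CPT 7 h profiles correlated with the controls at r = 0.740 to 0.792 across windows and with each other at 0.827.

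Named regions moved in both directions, and the 5 that rose passed the genome median, ending between 0.15 and 0.93. Chromosome 19, 960001 to 1260000, fell by 3.30 log2 (SE 0.204, adjusted p = 1.85e-09, limma), and chromosome 9, 139840001 to 140140000, changed by -3.16 (SE 0.186). Changes of -3.14 (SE 0.198), -3.08 (SE 0.174) and -3.07 (SE 0.168) were seen at chromosome 11, 320001 to 620000, chromosome 16, 1920001 to 2220000, and chromosome 17, 79040001 to 79340000. In caffeine alone these 5 falling windows lay at 2.82 to 3.36, each below both controls of its window. Without centring this did not hold on chromosomes 11, 16 and 17, because the uncentred medians of caffeine alone (-0.44, -0.50 and -0.41) lay above those of both controls (-0.75 and -0.63). In the other direction, chromosome 1, 2560001 to 2860000, rose by 1.69 (SE 0.110), from below -0.75 in both controls to 0.93 and 0.80. Chromosome 9, 137920001 to 138220000, rose by 1.65 (SE 0.124) and chromosome 8, 143040001 to 143340000, by 1.64 (SE 0.112). Chromosome 20, 45120001 to 45420000, rose by 1.55 (SE 0.114) and chromosome 12, 131520001 to 131820000, by 1.52 (SE 0.160). The chromosome 17 fall did not pass with profiles scaled to the same SD (-0.46, adjusted p = 0.407) or with quantile normalization (-0.44, adjusted p = 0.233), and that on chromosome 9 did not pass with quantile normalization (-0.38, adjusted p = 0.243).

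In all, limma called 6660 of 8350 windows at 7 h, 2911 earlier and 3749 later. Without centring the split was 4810 earlier and 2665 later. Scaling to the same SD left 4201 calls, 924 earlier and 3277 later, and quantile normalization 2856.

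**Figure D3:**
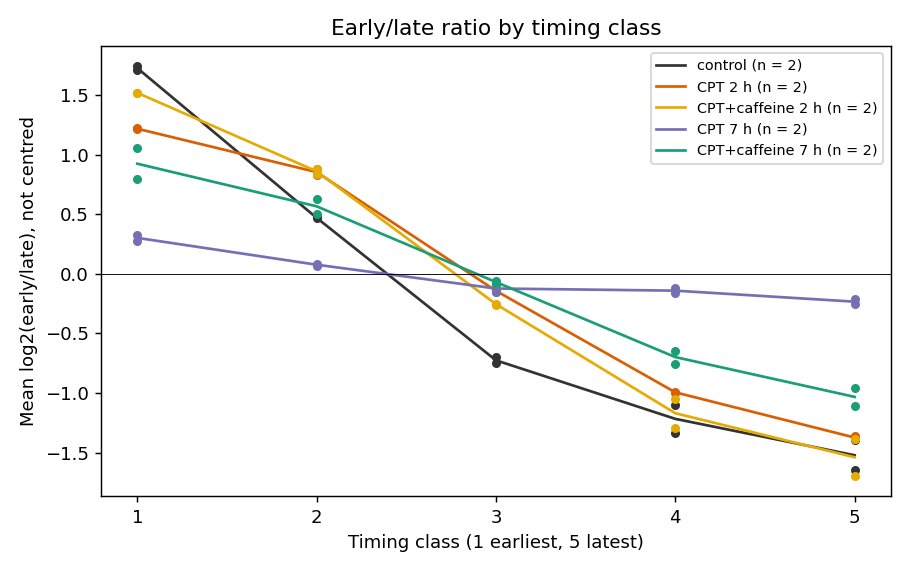
Mean uncentred log2 E/L by timing class (1 earliest, 5 latest); points are single profiles and lines the means of n = 2. The control line runs from 1.73 to -1.52 and the CPT 7 h line from 0.30 to -0.23.

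With caffeine added, both profiles at each time had a larger dynamic range and peak prominence than both with CPT alone. Over both times the differences were 0.34 and 0.35 (adjusted p = 0.0736 each, exact permutation test). Both lay at the smallest p this test allows, 0.0556, so no difference of any size could have passed. Valley depth and the prominence in the early and late libraries were at the same limit (adjusted p = 0.0736 each). Fine-scale share differed by -0.0083 (adjusted p = 0.364, same test). At 7 h the earliest class averaged 0.99 ± 0.17 and the latest -0.97 ± 0.12 log2 E/L, with a dynamic range of 0.771 ± 0.11 and a peak prominence of 0.552 ± 0.082 (SD, n = 2). At 2 h the earliest class averaged 1.77 ± 0.013, the dynamic range was 1.20 ± 0.091 and peak prominence 0.977 ± 0.030. At 7 h, chromosome 20, 61120001 to 61420000, lay 1.33 log2 higher with caffeine than without (SE 0.124, adjusted p = 8.06e-05, limma), and chromosome 10, 134080001 to 134380000, 1.32 higher (SE 0.145). Chromosome 22, 16000001 to 16300000, lay lower by -1.57 (SE 0.178) and chromosome 6, 61760001 to 62060000, by -1.35 (SE 0.199). Caffeine alone also lay below both controls there, on chromosome 22 at -1.36, -1.15 and -1.01 against -0.93 and -0.61 (not so without centring). On chromosome 6 it lay at -1.20, -0.87 and -1.29 against -0.37 and -0.41, and CPT+caffeine 7 h at -0.92 and -1.12. In the 2 windows that lay higher, the caffeine profiles did not all lie on 1 side of both controls. Of 8350 windows, 6590 differed at 7 h, 3409 earlier and 3181 later with caffeine. Scaling to the same SD left 3877 and quantile normalization 3289.

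At 2 h the window differences between CPT with and without caffeine were less secure. Chromosome 22, 21760001 to 22060000, was 1.17 log2 higher with caffeine (SE 0.143, adjusted p = 0.00299, limma) and chromosome 19, 1920001 to 2220000, 1.06 higher (SE 0.166). Chromosome 6, 46400001 to 46700000, at -0.49 (SE 0.134) and chromosome 3, 96320001 to 96620000, at -0.45 (SE 0.129) passed narrowly. In the 1 profile of caffeine alone at 2 h, these 2 windows lay at -1.56 and -1.49, and they lay higher at 7 and 24 h. The CPT+caffeine 2 h profiles lay at -1.53 and -1.24 on chromosome 6 and at -1.54 and -1.60 on chromosome 3. The count was 733 windows, 728 earlier and 5 later (407 and 144 without CPT+caffeine 2 h replicate 2), but it rested on the CPT 2 h replicates and on the scale. It was 2 without CPT 2 h replicate 1, and 0 by limma without replicate 2, where 1345 windows had an unadjusted p under 0.05. It was also 4 without centring, 133 without the filter on sparse windows, 0 with SD scaling and with quantile normalization, and 1237 by edgeR. All 4 named windows lost their call with SD scaling, with quantile normalization and without CPT 2 h replicate 2. With 1 profile left out in turn, all 4 kept their direction. The changes ranged from 1.01 to 1.33 on chromosome 22 and from 0.92 to 1.20 on chromosome 19. They ranged from -0.64 to -0.35 on chromosome 6 and from -0.59 to -0.30 on chromosome 3. The scalars were tested only over both times together, where no exact p below 0.0556 is possible.

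Both caffeine combinations still differed from control. At 2 h, 4029 windows differed, 384 earlier and 3645 later, or 3068 and 921 without centring. Chromosome 19, 960001 to 1260000, fell by 2.04 log2 (SE 0.204, adjusted p = 1.01e-05, limma) and chromosome 17, 79360001 to 79660000, changed by -1.70 (SE 0.137), while chromosome 12, 132800001 to 133100000, rose by 0.95 (SE 0.178) and chromosome 16, 960001 to 1260000, by 0.90 (SE 0.238). These windows are set against the same 2 control profiles as the CPT windows, so their recurrence is not independent. Quantile normalization left 0 of these calls by limma, with 1514 windows at an unadjusted p under 0.05 (edgeR without it gave 4272), and SD scaling left 857, without the named gains on chromosomes 12 and 16. At 7 h, 4539 windows differed, 700 earlier and 3839 later, or 4207 and 1719 without centring. The chromosome 19 window changed by -2.73 (SE 0.204) and chromosome 16, 320001 to 620000, by -2.56 (SE 0.184), while chromosome 9, 137920001 to 138220000, rose by 1.10 (SE 0.124) and chromosome 19, 33920001 to 34220000, by 0.95 (SE 0.123). Quantile normalization left 936 calls, without the chromosome 16 window (-0.82, adjusted p = 0.0751, limma). At 2 h the count was 2610 without control replicate 2, with 96 earlier, and 2599 without CPT+caffeine 2 h replicate 1, with 199 earlier.

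Between 2 and 7 h of CPT, the named late regions rose and the named early regions fell. Chromosome 8, 142720001 to 143020000, rose by 2.06 log2 (SE 0.141, adjusted p = 1.23e-06, limma) and chromosome 12, 131520001 to 131820000, by 2.00 (SE 0.160). Chromosome 20, 61120001 to 61420000, changed by -1.72 (SE 0.124) and chromosome 16, 960001 to 1260000, by -1.73 (SE 0.238). With profiles scaled to the same SD the chromosome 16 window turned to 1.03 and the chromosome 20 window did not pass. In all 7427 windows differed, 3555 earlier and 3872 later at 7 h. SD scaling left 3982 and quantile normalization 3475.

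Across all profiles, timing peaks were lower with CPT. Peak prominence averaged 0.590 in the 8 CPT profiles and 1.16 in the 5 without CPT, a difference of -0.57 log2 (exact permutation test, two-sided, p = 0.00622, adjusted p = 0.0272), and each of the 8 lay below each of the 5. At 2 h alone the difference was -0.29 and at 7 h -0.85, each with an adjusted p of 0.0272 by the same exact test. These tests shuffled single profiles, so replicates of a condition counted as separate units and the p-values may be too small. At 7 h, valley depth (0.74, from -1.05 to -0.30, so shallower valleys), dynamic range (-0.76) and prominence in the early libraries (-0.60) also passed. Each had an adjusted p of 0.0272 by the same exact test, with all 4 CPT profiles on 1 side of the 5 others. The prominence of peaks in the early libraries was lower by -0.46 over both times (adjusted p = 0.0272, exact permutation test), and in the late libraries the dip at peaks was shallower at 7 h by 0.25 (adjusted p = 0.0476). At 2 h the late-library dip differed by -0.018 (adjusted p = 0.675, exact permutation test). Dynamic range over both times (-0.46, adjusted p = 0.0571, exact permutation test) and at 2 h (-0.16, adjusted p = 0.0635) did not pass, nor did early-library prominence at 2 h (-0.31, adjusted p = 0.0571). When peaks were taken from the CPT profiles themselves, the difference in peak prominence did not pass over both times (-0.37, adjusted p = 0.0874, exact permutation test) or at 2 h (-0.078, adjusted p = 0.276), nor did the late-library dip at 7 h (0.12, adjusted p = 0.159), which also did not pass with flanks of 800 kb. SD scaling, which has no meaning for dynamic range, ended each of the other calls, although peak prominence and early-library prominence at 7 h kept the smallest unadjusted p the exact test allows, 0.00794.

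**Figure D4:**
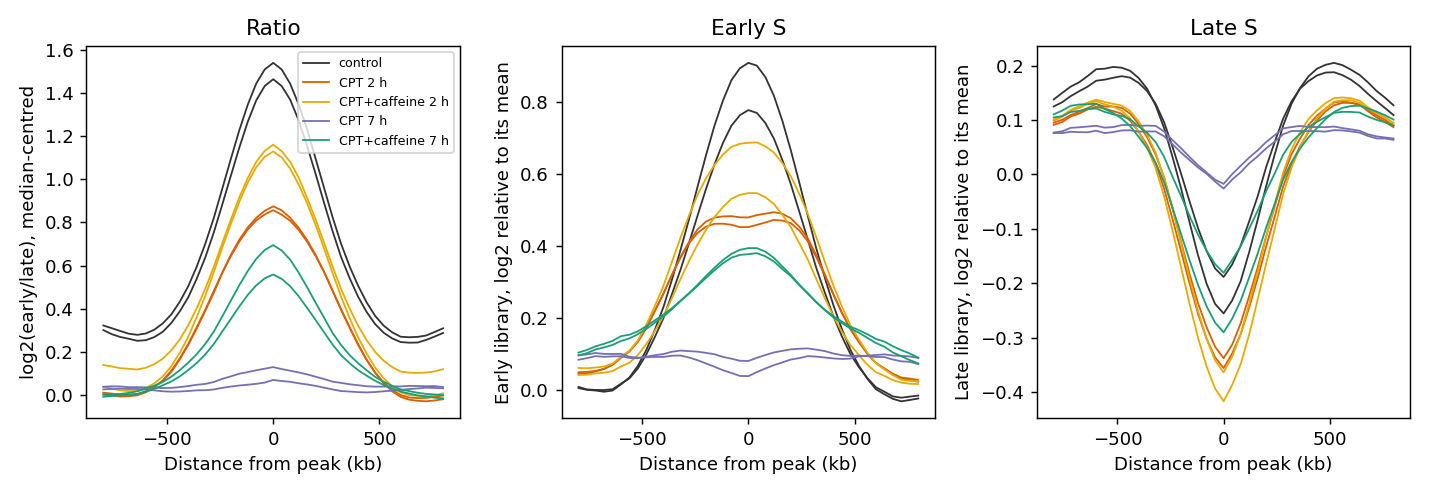
Mean log2 E/L (left), early library (middle) and late library (right) against distance in kb from the consensus peaks; each line is 1 profile of the 5 conditions with 2 replicates. In the early library the control profiles peak sharply while the CPT 2 h profiles form a plateau, and the dip of the late library remains in CPT 2 h.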

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

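The class values below and the tests of gate exchange, depth and of dilution by DNA of any profile, as well as the dilution test at 2 h, were chosen only after the result was seen.

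The effect of caffeine under CPT differed between 7 h and 2 h in 3145 of 8350 windows by limma's test of the interaction, 1120 with a more positive effect at 7 h and 2025 with a more negative one. This difference between time points is what singled the result out. Of the named windows, those with the largest difference in each direction were chromosome 22, 48640001 to 48940000, at -1.66 log2 (SE 0.162) and chromosome 18, 53120001 to 53420000, at 1.16 (SE 0.150). The count was lower without CPT 2 h replicate 1 (1504) or 2 (1900), CPT 7 h replicate 1 (1625) or 2 (1418), CPT+caffeine 2 h replicate 2 (1693) and CPT+caffeine 7 h replicate 2 (1238). Across these 6 omissions, 342 to 591 windows had a more positive effect at 7 h. Without centring the split was 1634 to 1456.

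After 7 h of CPT the E/L profile was nearly flat. Lower depth is argued against, since the smallest CPT 7 h library held 4419192 reads and the smallest control library 3900012. Exchange of cells between the sort gates would keep the range of the mean of both libraries, which differed from the lowest CPT-free profile by -0.23 log2, but it cannot be told apart, because that range was 0.32 and 0.27 at 7 h and already 0.32 and 0.36 after 2 h of CPT, where E/L was not flat, and was lower in caffeine alone (0.55 to 0.76) than in control (1.18 and 0.98). Dilution of both libraries alike by DNA of any profile stays open: the early minus late difference was 16.0% to 21.6% of control over the classes in replicate 1 and 11.4% to 20.1% in replicate 2, and classes 1 and 5 differed by 3.12 percentage points in the nearer replicate, although a bound of 10 points is wide beside such values. Dilution by a flat background came within 0.058 log2 in the nearer replicate, but that test cannot tell it apart from others, because its bound of 0.2 log2 was as wide as the predicted values. A strictly flat background would add no pattern common to both libraries. The early and late libraries correlated at 0.756 and 0.790 after 7 h of CPT against -0.017 and -0.084 in control. These values argue against a strictly flat background as the whole cause, but not against one with a profile of its own. Loss of timing in the cells themselves was not tested.

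After 2 h of CPT, uncentred E/L was lower in class 1 (1.22 against 1.73 in control) but higher in class 2 (0.85 against 0.47, and 0.61 to 0.71 in caffeine alone); with centring class 2 was lower, at 0.99 against 1.16. Dilution of both libraries by unlabelled DNA would move class 2 toward 0, but its uncentred E/L lay 0.35 log2 further from 0 than in the higher control. That rise is part of the pattern itself, so it is no separate test. Class 5 is not part of the pattern. Starting from the control profiles, a flat background set from class 1 (31.6% and 31.1% in the replicates) predicted -0.84 and -0.85 there. The observed values were -1.43 and -1.40. Cells of the late gate in the early gate would, starting from the control profiles, need a share of 39.5% and 38.8% in the replicates and then miss the early library by 0.29 log2 in the class predicted worst. The class 5 values argue against dilution, and the early library against late-gate cells, as the whole cause. A combination of the 2 was not tested. A lower rate of initiation in the earliest regions stays open and was not tested.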

How the results depend on the processing

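The edgeR fits, SD scaling of class gaps and leaving profiles out of class gaps were chosen after seeing the data. Pseudocounts of 0.1 and 10 changed no call listed here, nor did the stricter filter for the windows it kept. Shifting windows by 160 kb could not test the named windows, because none of them is among the shifted ones. For window counts, shifting gave 768 against 733 for CPT+caffeine against CPT at 2 h. It gave 3975 against 4029 for CPT+caffeine 2 h against control. Not run were the gene lists (no annotation of the build), DESeq2, SD scaling of dynamic range (void) and a block for scalars other than CPT+caffeine against CPT. Depth gave a counting error of 0.088 to 0.102 log2 per window. In the self-test limma recovered 62% of windows changed by 0.5 log2. Far fewer windows were changed there than any contrast called, so this does not bound recovery in the data. The cause was not tested unless stated.

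Replicate numbers did not pair the samples in the same direction throughout: deviations of same-numbered samples correlated between -0.41 and 0.41. The values were 0.41 for control with CPT+caffeine 2 h, -0.41 for control with CPT+caffeine 7 h and -0.39 for the 2 CPT+caffeine groups. The others lay between -0.15 and 0.045. These correlations do not by themselves show deviations shared between samples, because dynamic range also differed between the replicates. In replicates 1 and 2 it was 1.29 and 1.21 in control, 1.26 and 1.13 in CPT+caffeine 2 h, and 0.69 and 0.85 in CPT+caffeine 7 h. Whether such a difference in amplitude or a batch numbered otherwise underlies the correlations was not tested. With the replicate block the window counts were 4066 for CPT 2 h, 6603 for CPT 7 h, 3887 for CPT+caffeine 2 h and 4428 for CPT+caffeine 7 h against control, 590 and 6484 for CPT+caffeine against CPT at 2 and 7 h, 7375 for CPT 7 h against 2 h and 2838 for the interaction. The block ended the call of 1 named window, chromosome 3, 96320001 to 96620000 (adjusted p = 0.0513 by limma). For the scalars of CPT+caffeine against CPT the block left the values unchanged, with dynamic range at 0.34 (exact permutation p = 0.125). That is the smallest p the blocked test allows, so it does not show a weaker effect.

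Windows: scaling to the same SD gave 2137 (CPT 2 h), 4201 (CPT 7 h) and 857 (CPT+caffeine 2 h) against control, 0 and 3877 for CPT+caffeine against CPT at 2 and 7 h, 3982 for CPT 7 h against 2 h and 2562 for the interaction. Quantile normalization gave 428, 2856, 0 and 936 against control (CPT 2 h, CPT 7 h, CPT+caffeine 2 h and 7 h), 0 and 3289 for CPT+caffeine against CPT, 3475 for CPT 7 h against 2 h and 1993 for the interaction. Where limma gave 0, unadjusted p lay under 0.05 in 234 windows with SD scaling and 418 with quantile normalization for CPT+caffeine against CPT at 2 h, and in 1514 for CPT+caffeine 2 h against control; edgeR without these scalings gave 1237 and 4272. CPT+caffeine against CPT at 2 h also gave 4 uncentred, 4 with the deposited ratios and 133 without the filter. Leaving out a profile gave 2599 to 4113 for CPT+caffeine 2 h against control, 0 to 907 for CPT+caffeine against CPT at 2 h (0 without CPT 2 h replicate 2, with 1345 unadjusted) and 1238 to 3867 for the interaction.

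Scalars that passed and then did not: SD scaling gave peak prominence -0.20 over both times, -0.11 at 2 h and -0.30 at 7 h, valley depth at 7 h 0.24, early-library prominence -0.28 over both times and -0.40 at 7 h, and late-library prominence at 7 h 0.12; peak and early-library prominence at 7 h kept the smallest exact p, 0.00794, with adjusted p at 0.0529. Peaks from the CPT profiles gave peak prominence -0.37 over both times and -0.078 at 2 h and late-library prominence at 7 h 0.12, and flanks of 800 kb gave the last 0.28. Controls alone as the CPT-free group gave dynamic range at 7 h -0.74, peak prominence -0.56, -0.28 and -0.84 (both times, 2 h, 7 h), valley depth at 7 h 0.73, early-library prominence -0.50 and -0.65 and late-library prominence at 7 h 0.19; there only 2 profiles remain, so fewer arrangements raise the smallest p. Passing only under an alternative were fine-scale share at 7 h with flanks of 800 kb (-0.118), valley depth over both times with peaks from caffeine (0.45) or control profiles (0.47), early-library prominence at 2 h with the same (-0.33 and -0.32), and late-library prominence over both times with control peaks (0.18).

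Leaving out a profile also leaves fewer arrangements, which ended every call at 7 h, and the peak prominence call over both times in 9 of 13 cases and at 2 h in 7 of 9, and the early-library call over both times in 8 of 13. Dynamic range over both times passed without CPT+caffeine 2 h replicate 1 (-0.53) or 2 (-0.51), and dynamic range (-0.21) and early-library prominence (-0.35) at 2 h and valley depth over both times (0.49) without replicate 1. The ranges were -0.53 to -0.38, -0.21 to -0.13 and -0.88 to -0.67 for dynamic range (both times, 2 h, 7 h), -0.63 to -0.49, -0.34 to -0.25 and -0.95 to -0.76 for peak prominence, 0.34 to 0.49 and 0.65 to 0.84 for valley depth (both times, 7 h), -0.50 to -0.42, -0.36 to -0.28 and -0.65 to -0.55 for early-library prominence, and 0.21 to 0.30 for late-library prominence at 7 h.

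Class gaps against control: classes from the control mean gave -0.98 (classes 1 to 3) and 0.12 (3 to 5) for CPT 2 h, -0.54 and 0.13 for CPT+caffeine 2 h and, reversed from 0.17 ± 0.18, -0.18 (3 to 5) for CPT+caffeine 7 h. Classes from the caffeine mean gave -1.12 and -0.71 (1 to 3) at 2 h without and with caffeine. SD scaling gave -0.64 and -0.47 (1 to 3) there, -0.29 and -0.19 for CPT 7 h, and -0.67 and 0.61 for CPT+caffeine 7 h. SD scaling reversed 1 named window, chromosome 16, 960001 to 1260000, to 1.03 for CPT 7 h against 2 h; it divides CPT 7 h profiles by a small SD and so enlarges their noise too. Of the named windows' other alternatives, 445 kept direction and call and 36 lost the call, and with a profile left out 422 kept and 18 lost it. Other settings left 163 scalar values and 78 window counts on their side of the threshold or within 1.5 times.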

Other observations

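The position of timing peaks was examined only after peak prominence at 2 h had been found to differ by -0.078 with peaks taken from CPT profiles, the test of less precise placement was stated only after the share near control peaks was known, and the class means of both libraries were also examined after exploratory results.

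In class 2 the 156 valleys lay -0.176 ± 0.045 log2 from their flanks after 2 h of CPT against -1.10 ± 0.030 in control (SD, n = 2), and -1.04 to -0.902 in caffeine alone. The 715 valleys of class 5 lay at -0.956 ± 0.031 against -0.785 ± 0.073, within the -1.07 to -0.81 of caffeine alone. With caffeine added the class 2 valleys lay at -0.502 ± 0.060. By chromosome, the early chromosomes 17, 19 and 22 averaged 1.30, 1.29 and 1.40 in control, 0.65, 0.55 and 0.72 after 2 h of CPT, and 0.20, 0.21 and 0.28 after 7 h.

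Of CPT 2 h peaks, 44.4% in replicate 2 and 42.5% in replicate 1 lay within 120 kb of a peak of the control mean, against 69.1% to 73.5% for caffeine alone, 49.8% to 58.0% for CPT with caffeine and 17.1% for random positions in the same replicate. Less precise placement of lower peaks is argued against, because 67.8% and 66.6% of these peaks lay within 120 kb of a peak of the other CPT 2 h replicate, at least 22.2 percentage points more. Whether CPT moves timing peaks stays open, because the 44.4% is the observation itself and no separate test was run, and splitting or merging of lower peaks was not tested either. The control comparison used the mean of 2 profiles and the replicate comparison a single profile, and after 7 h of CPT the order was opposite, with 34.7% and 23.5% of peaks near a control peak and 18.3% and 19.7% near one of the other replicate.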
